A study of Mus musculus with 109 samples.

How the data were processed

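The RNA values were 4 tables of normalised values deposited by the authors, used as signal in normalised reads per gene and library. Per the file headers the columns are normalised, and per the labels the libraries are 3' tag libraries made by MARS-seq. Per the submitters' processing notes reads were mapped to mm10. The aligner, the counting program and the method behind the size factors are not given in the sources used here. Dividing each column by its smallest step gave whole reads for 100 percent of the values within a tolerance of 0.01, and these recovered whole reads were used only for edgeR and DESeq2. Recovered reads per library ran from 685687 to 1741686 in the table of controls, 558878 to 1875460 in the Il10ra mutant table, 540642 to 2489084 in the double mutant table and 558105 to 1496077 in the untreated table. The tables held 26, 48, 38 and 19 libraries, and several libraries stood in more than 1 table. The control libraries held the same recovered reads in the first 2 tables for all of 12270 genes, with 0 differing, so these tables are not independent. Genes whose names had been turned into dates (17, 18, 18 and 17) were left out, and 12498, 12798, 13390 and 11549 genes remained.

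Samples were assigned to groups, genotypes, times and experiments from the labels alone. Each group was fitted with an additive term for the experiment named in the labels. The day 7 and the C57BL/6 libraries each came from an experiment of their own, which no term could separate from the group. Day 7 was fitted together with the other control groups and the terms of their experiments, and the C57BL/6 comparison had no experiment term. A library of the doubly floxed controls at 48 h had labels naming different genotypes and was left out of the tests. An untreated double mutant library, whose column name calls it a mistake, had labels without conflict and was kept. Il10ra mutants at 48 h came from 2 experiments and stood in both mutant tables. The fold changes of the first table therefore rested on 3 of these libraries and those of the second on the other two.

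Groups, the 14 planned RNA comparisons, tests, filters, 25 gene lists and alternative settings were fixed before the data were examined. The comparison of untreated C57BL/6 microglia with untreated floxed controls was chosen after the data were seen. Values were taken as log2 of value plus 1, and genes with a value of at least 5 in at least as many libraries as the smallest group (minimum 2) were tested, giving 11103, 11555, 11800 and 10367 genes. limma with a trend gave fold changes, standard errors and p, adjusted by Benjamini-Hochberg within each comparison, and called at an adjusted p under 0.05. These p-values measure the spread between the samples of a group. Named genes were the 10 largest rises and falls per comparison among called genes with log2 of at least 1 and a mean of at least 20 in 1 group, the targeted genes, and the 4 genes of lowest p in each list. For these rises and falls, every library of the first group also had to lie beyond the mean of the second. Predicted genes with Gm or Rik names were left out, 83 of them in controls at 6 h. Largest rises and falls are meant within this rule. Cx3cr1 in comparisons where it did not pass, and Acod1, P2ry12 and Adgrg1 outside that rule were chosen after their values were seen. Averages within an experiment are plain means of its libraries.

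Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 336 planned tests. Of 25 lists 24 had enough genes to test. They covered homeostatic microglia, cytokines and chemokines, NF-kB targets, interferon response, IL-10 and STAT3 response, neurodegeneration-associated genes, MHC classes I and II, complement and phagocytosis, inflammasome, proliferation, glycolysis, cholesterol and lysosome, immediate early genes, TGF-beta signalling, ribosomal proteins and markers of 8 other cell types. List counts are given over all genes and as adjusted over the list alone.

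The ATAC data were peak lists deposited by the authors, 1 per library. Per the submitters' processing notes they were made with HOMER on mm9, and the aligner is not given in the sources used here. Per the file headers each list was called with the library's own tags as the input, a fragment length of 300 bp, a false discovery rate of 0.001 and a fold of 4 over input and over local tags. Peak score and the deposited ratio over input (fold) are units of the authors, and the ratio was not used here because the input was the library itself. The tag signal of the peaks, per the file headers scaled to a fixed number of tags, was not compared between libraries. The lists held 264891 peaks at 228938 distinct positions. Peaks per library and tags were compared, after averaging the 2 runs of each untreated number, by exact permutation over 70 splits, whose smallest p is 0.0286. Overlap of at least 1 bp was measured between libraries with at least 1000 peaks, 14 samples in all, and tested by exact permutation over 3153150 labelings. No gene was assigned to a peak, because no mm9 gene annotation was used here.

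New reads were simulated for each gene from its mean over all libraries and its dispersion. They held no group or experiment effects, and genes were drawn independently. Real libraries share structure that these reads lack, so the shares recovered may be too high and the false calls too few. Changes of known size were given to 50 genes at each of log2 -2, -1, 1 and 2, and the share recovered was counted in each comparison. In controls it was 83.7, 34.7, 32 and 79.6 percent at 6 h, 87, 37.5, 46 and 82 percent at 24 h, 75, 53.1, 44 and 88 percent at 48 h, and 89.8, 58.3, 54 and 92 percent at day 7. For Il10ra mutants it was 76, 73.5, 59.2 and 98 percent untreated, 80.4, 60, 58 and 92 percent at 6 h, 81.6, 53.2, 51 and 84 percent at 24 h, and 81.6, 50, 69.4 and 80 percent at 48 h. The interaction gave 74, 23.4, 28.6 and 68 percent. For double mutants it was 78.7, 55.1, 75.5 and 89.8 percent untreated, 77.6, 72, 63.3 and 90 percent at 6 h, and 77.6, 40.8, 42.6 and 91.8 percent at 48 h. Il10ra mutants against doubly floxed controls gave 68.8, 31.2, 32.7 and 75.5 percent, double against Il10ra mutants 66.7, 28.6, 30.6 and 78 percent, and C57BL/6 against floxed controls 95.7, 64, 66 and 94 percent. False calls ran from 1 to 11.8 percent of the calls.

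Alternatives tried were a pseudocount of 5, no filter, quantile normalization, rescaling to the upper quartile, no experiment term, a single shared experiment, a replicate block, each library left out in turn, the library with conflicting labels kept, edgeR quasi-likelihood and DESeq2. After the data were seen, the other shared experiment, a neutrophil covariate and the omission of single libraries of low mitochondrial share, of low Cx3cr1 or with a column name calling them a mistake were added. Counts that equal an animal number in the labels are rounded to 2 digits elsewhere. They were 113 genes by DESeq2 in double mutants at 6 h, 108 there without double mutant library 3, 146 in Il10ra mutants at 6 h without control 4 and 128 at 24 h without mutant library 5. At 24 h 128 genes were higher in Il10ra mutants, and at day 7 106 were lower. Gene list calls numbered 109, and the outlier test covered 116 sets of libraries. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, statmod 1.5.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.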

Results

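The data were 89 RNA libraries and 20 ATAC libraries of mouse brain microglia, sorted by flow cytometry on CD45 and CD11b. Mice were untreated or received an intraperitoneal dose of lipopolysaccharide (LPS). Floxed Il10ra controls without Cre gave 6 untreated libraries and 6, 4, 6 and 4 libraries at 6 h, 24 h, 48 h and day 7. Il10ra mutants, which carried the Cx3cr1-CreER allele, gave 9 untreated libraries and 7, 5 and 5 at 6, 24 and 48 h. Controls floxed for both Il10ra and Tnf gave 6, 5 and 6 libraries (untreated, 6 h, 48 h), and double mutants of Il10ra and Tnf gave 5, 6 and 4. Libraries held from 540642 to 2489084 reads in the tables used. RNA values are normalised reads, given as mean ± SD over libraries, and log2 fold changes are given ± standard error from limma with Benjamini-Hochberg adjusted p.

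The first question was how control microglia changed over time after LPS. At 6 h (6 against 6 libraries) 2264 genes were higher and 2341 lower than without LPS. The chemokine Ccl5 rose from 22.2 ± 7.86 to 2792 ± 375 normalised reads (log2 6.93 ± 0.37, adjusted p = 4.08e-14). The interleukin 1 receptor antagonist Il1rn rose from 4.78 ± 2.36 to 673 ± 113.2 (log2 6.82 ± 0.58, adjusted p = 2.52e-10), and the interleukin 1 beta gene Il1b from 11.8 ± 4.34 to 549 ± 93.1 (log2 5.71 ± 0.32, adjusted p = 1.06e-13). Tnf rose from 31.2 ± 7.48 to 706 ± 302 (log2 5.11 ± 0.39, adjusted p = 4.48e-11). Spp1, Trem1, Cd40 and the acute phase gene Saa3 were also among the largest rises (log2 6.12, 6.04, 5.80 and 5.72). The largest fall was that of the transcriptional corepressor Cbfa2t3, from 131 ± 41.4 to 2.61 ± 3.21 (log2 -6.04 ± 0.43, adjusted p = 1.02e-11). The microglial purinergic receptor P2ry12 fell from 4644 ± 557 to a mean of 559 (log2 -2.88 ± 0.24, adjusted p = 2.56e-10), Gpr34 from 1214 ± 504 to 46.1 ± 31.96 (log2 -4.71 ± 0.71, adjusted p = 4.59e-06), and the transcription factor Sall1 by log2 1.69.

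Gene lists moved with these genes at 6 h. Of 20 homeostatic microglia genes 17 fell and 0 rose (17 when adjusted over the list alone, median log2 -1.36, camera adjusted p = 1.05e-07, adjusted p = 0.215 with an estimated correlation). Of 18 inflammatory cytokine and chemokine genes 17 rose (18 over the list alone, median log2 4.17, camera adjusted p = 7.01e-16, adjusted p = 0.031 with an estimated correlation). All 23 interferon response genes rose (23 over the list alone, median log2 3.39, camera adjusted p = 7.01e-16, adjusted p = 0.148 with an estimated correlation). Of 21 NF-kB target genes 17 rose (17 over the list alone, camera adjusted p = 5.03e-11, adjusted p = 0.0788 with an estimated correlation). Of 15 genes of the IL-10 and STAT3 response 12 rose and 1 fell (13 and 1 over the list alone, camera adjusted p = 2.44e-09, adjusted p = 0.00675 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose from 177 ± 40.6 to 2232 ± 856 (log2 3.92 ± 0.29, adjusted p = 2.32e-11).

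Further lists rose at 6 h by the preset camera test. They were MHC class I (8 of 13 genes, 10 over the list alone, adjusted p = 0.000176, adjusted p = 0.148 with an estimated correlation), immediate early genes (11 of 15, 11 over the list alone, adjusted p = 9.49e-07, adjusted p = 0.208 with an estimated correlation) and ribosomal proteins (12 of 20, 12 over the list alone, adjusted p = 0.000675, adjusted p = 0.417 with an estimated correlation). Glycolysis genes gave 8 higher and 1 lower of 12 (8 and 1 over the list alone, adjusted p = 0.00113, adjusted p = 0.058 with an estimated correlation). Lists that did not pass were neurodegeneration-associated genes (7 higher and 5 lower of 19, adjusted p = 0.461), inflammasome genes (3 and 1 of 9, adjusted p = 0.349) and cholesterol and lysosome genes (5 and 2 of 10, adjusted p = 0.356). TGF-beta signalling genes (0 and 4 of 11, adjusted p = 0.383) did not pass either, although Tgfbr1 fell by log2 1.21. The 6 MHC class II genes had a median of log2 -0.02 and a mean of log2 0.25 (camera adjusted p = 0.827). Among other-cell markers, 2 of 2 lymphocyte genes fell (camera adjusted p = 0.00638, adjusted p = 0.0789 with an estimated correlation), while astrocyte, oligodendrocyte, neuron and endothelial markers did not pass (adjusted p = 0.726, 0.562, 0.913 and 0.46). Neutrophil (1 higher and 1 lower of 10, adjusted p = 0.743), border macrophage (1 and 1 of 8, adjusted p = 0.827) and monocyte markers (5 and 1 of 9, 7 and 1 over the list alone, adjusted p = 0.0551) did not pass either, although the monocyte markers Fn1 (log2 4.70, adjusted p = 1.17e-06) and Ccr2 (log2 -1.997, adjusted p = 0.00389) were called.

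At 24 h (4 against 6 libraries) 1574 genes were higher and 1670 lower than without LPS. The decoy receptor gene Il1r2 had the largest rise, from 2.89 ± 1.98 to 525 ± 277 (log2 7.13 ± 0.69, adjusted p = 8.07e-09), followed by Saa3 (log2 7.07 ± 0.73, adjusted p = 2.74e-08) and Lrg1 (log2 6.16). Tnf stood at 668 ± 488 (log2 4.49 ± 0.39, adjusted p = 1.47e-09), and P2ry12 at 575 ± 136 (log2 -2.88 ± 0.24, adjusted p = 8.45e-10). Il10ra itself fell from a mean of 589 to 401 ± 26.2 (log2 -0.54 ± 0.18, adjusted p = 0.0258). Duoxa1, listed at 0 in all 4 libraries at 24 h, averaged 22.7 ± 2.79 without LPS. Of the 20 homeostatic genes 17 fell (18 over the list alone, median log2 -1.69, camera adjusted p = 1.85e-14, adjusted p = 0.0606 with an estimated correlation), and of the cytokine genes 15 rose (15 over the list alone, median log2 2.99, camera adjusted p = 2.83e-13, adjusted p = 0.0496 with an estimated correlation).

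At 48 h (6 against 6 libraries) 1231 genes were higher and 877 lower than without LPS. Saa3 rose from 24.0 ± 18.6 to 3200 ± 1338 (log2 6.56 ± 0.66, adjusted p = 2.39e-08), Lrg1 by log2 6.45 ± 0.55 and Fn1 by log2 6.11 ± 0.59. Tnf was still higher at 218 ± 74.5 (log2 2.55 ± 0.36, adjusted p = 4.87e-06), and P2ry12 still lower at 1280 ± 400 (log2 -2.04 ± 0.22, adjusted p = 7.74e-08). Complement gene C4b rose from 7.59 ± 3.33 to 339 ± 120 (log2 4.88 ± 0.44, adjusted p = 2.56e-09). Of 15 complement and phagocytosis genes 14 rose (14 over the list alone, camera adjusted p = 2.46e-13, adjusted p = 0.00675 with an estimated correlation). Of 16 proliferation genes 14 rose (16 over the list alone, median log2 1.98, camera adjusted p = 2.87e-09, adjusted p = 0.0788 with an estimated correlation), among them thymidine kinase Tk1, from 5.22 ± 1.497 to 30.9 ± 14.8 (log2 2.50 ± 0.42, adjusted p = 7.27e-05). H2-Aa, an MHC class II gene, fell from 103 ± 34.3 to 31.7 ± 14.4 (log2 -2.11 ± 0.35, adjusted p = 6.14e-05), whereas Cd74 rose by log2 0.73 ± 0.22. Of the homeostatic genes 13 fell (14 over the list alone, camera adjusted p = 5.91e-08, adjusted p = 0.208 with an estimated correlation). The count of genes at 48 h was 1390 without untreated control 4. Only part of the untreated libraries shared an experiment with each time point, so the size of the response also depends on an additive experiment term.

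At day 7 (4 against 6 libraries, in an experiment of its own) 455 genes differed from untreated, 349 of them higher. The largest rises were of haemoglobin genes, with Hbb-bs going from 27.1 ± 64.2 to 1250 ± 432 (log2 8.35 ± 1.21, adjusted p = 3.55e-05), and of neutrophil granule genes, with S100a8 going from 48.9 ± 25.8 to 1763 ± 1542 (log2 5.37 ± 0.83, adjusted p = 9.07e-05). Of 10 neutrophil markers 8 rose (9 over the list alone, median log2 4.91, camera adjusted p = 9.82e-16, adjusted p = 0.0344 with an estimated correlation). Of 9 monocyte markers 8 rose (9 over the list alone, median log2 2.94, camera adjusted p = 4.17e-16, adjusted p = 0.00029 with an estimated correlation), and of 8 border macrophage markers 7 rose (7 over the list alone, median log2 3.29, camera adjusted p = 1.08e-15, adjusted p = 0.00654 with an estimated correlation). MHC class II gene H2-Aa, which had fallen at 48 h, was at 943 ± 269 against 103 ± 34.3 (log2 3.21 ± 0.32, adjusted p = 1.45e-07), and Cd74 rose from 103 ± 19.4 to 623 ± 180 (log2 2.57 ± 0.21, adjusted p = 2.52e-09). The border macrophage gene Mrc1 rose by log2 3.22 ± 0.54 (adjusted p = 0.000246). Falls were smaller, led by Hspa1b (log2 -2.84 ± 0.83, adjusted p = 0.048) and the stress gene Ddit4 (log2 -2.12 ± 0.51, adjusted p = 0.012). Tnf was no longer called (56.2 ± 25.2 against 31.2 ± 7.48, log2 0.77, adjusted p = 0.228), and of the 20 homeostatic genes 1 fell (1 over the list alone, median log2 -0.16, camera adjusted p = 0.0407, adjusted p = 0.699 with an estimated correlation). Of 15 immediate early genes 10 rose and 1 fell (12 and 2 over the list alone, median log2 0.93, camera adjusted p = 5.84e-12, adjusted p = 0.0649 with an estimated correlation), among them Fosb (log2 3.12 ± 0.47, adjusted p = 6.68e-05) and Fos (log2 1.69 ± 0.24, adjusted p = 2.62e-05). Untreated C57BL/6 libraries, also from an experiment of their own, had higher Hbb-bs (log2 5.95) and Fosb (log2 4.23) than untreated floxed controls too. With a neutrophil marker covariate, chosen after the values were seen, 7 genes were left, but 77 percent of the variance of that covariate lay between the groups. Without day 7 library 1 the count was 231.

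**Figure D1:**
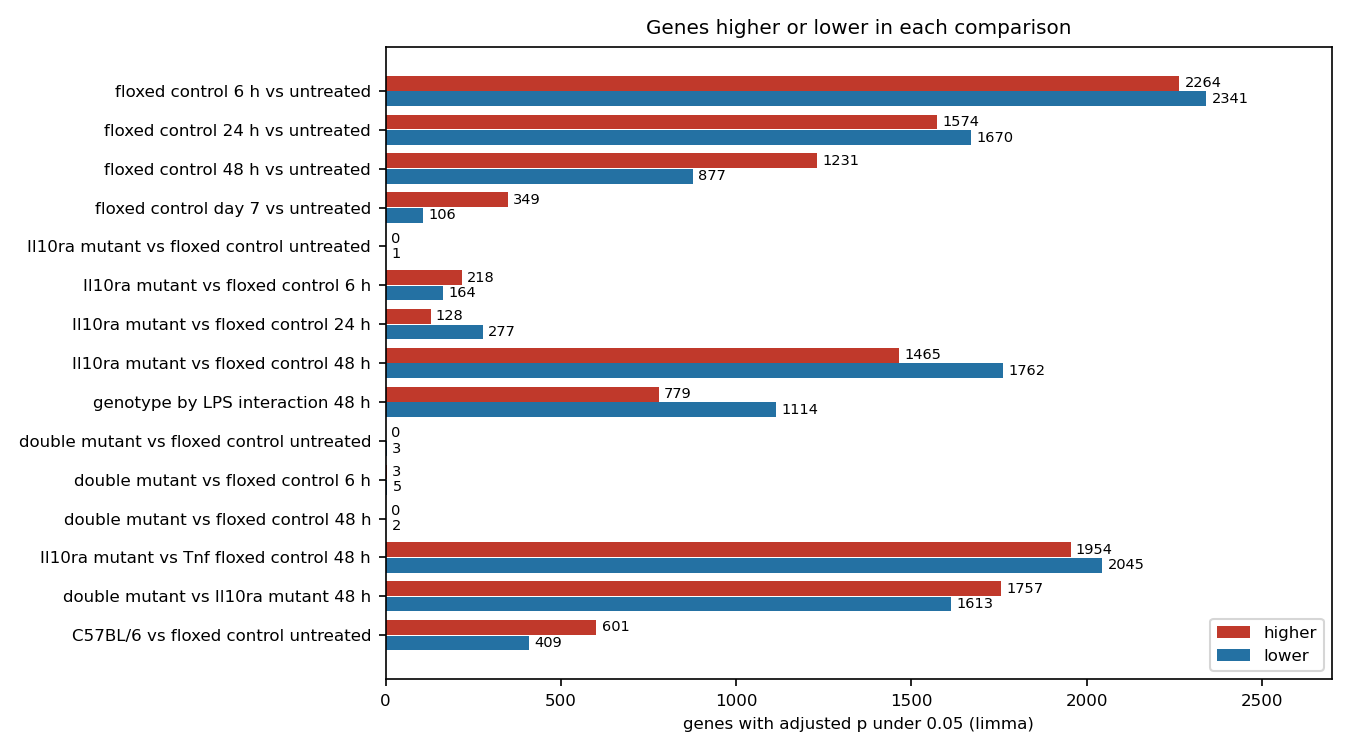
Number of genes higher (red) and lower (blue) in each of the 15 comparisons at limma adjusted p under 0.05, horizontal axis in genes. At 48 h 1465 genes were higher and 1762 lower in Il10ra mutants than in controls, and 0 and 2 in double mutants.

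The knockout comparisons start from the targeted genes. Il10ra in controls without LPS averaged 542 ± 103 normalised reads, and over all times every control library lay at 268.5 or above. Il10ra mutants averaged 63.1 ± 33.2 without LPS and 47.1 ± 12.2, 27.2 ± 10.2 and 47.6 ± 11.4 at 6, 24 and 48 h, and no mutant library exceeded 123.6. The falls were log2 -3.25 ± 0.25 (adjusted p = 3.69e-13), -2.94 ± 0.26 (adjusted p = 3.1e-11), -3.82 ± 0.31 (adjusted p = 3.9e-12) and -3.48 ± 0.32 (adjusted p = 4.74e-11). In double mutants Il10ra averaged 27.0 ± 10.7, 23.5 ± 8.79 and 38.5 ± 30.4 (without LPS, 6 h, 48 h) against 483 ± 42.4, 340 ± 87.6 and 414 ± 53.3 in their controls. Tnf in the same double mutants averaged 3.83 ± 5.38, 10.9 ± 11.4 and 6.09 ± 2.27 against 14.5 ± 7.51, 399 ± 162 and 135 ± 62.6. These falls of Tnf were log2 -2.29 ± 0.42 (adjusted p = 0.0131), -5.66 ± 0.42 (adjusted p = 2.85e-12) and -3.94 ± 0.45 (adjusted p = 7.13e-07).

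**Figure D2:**
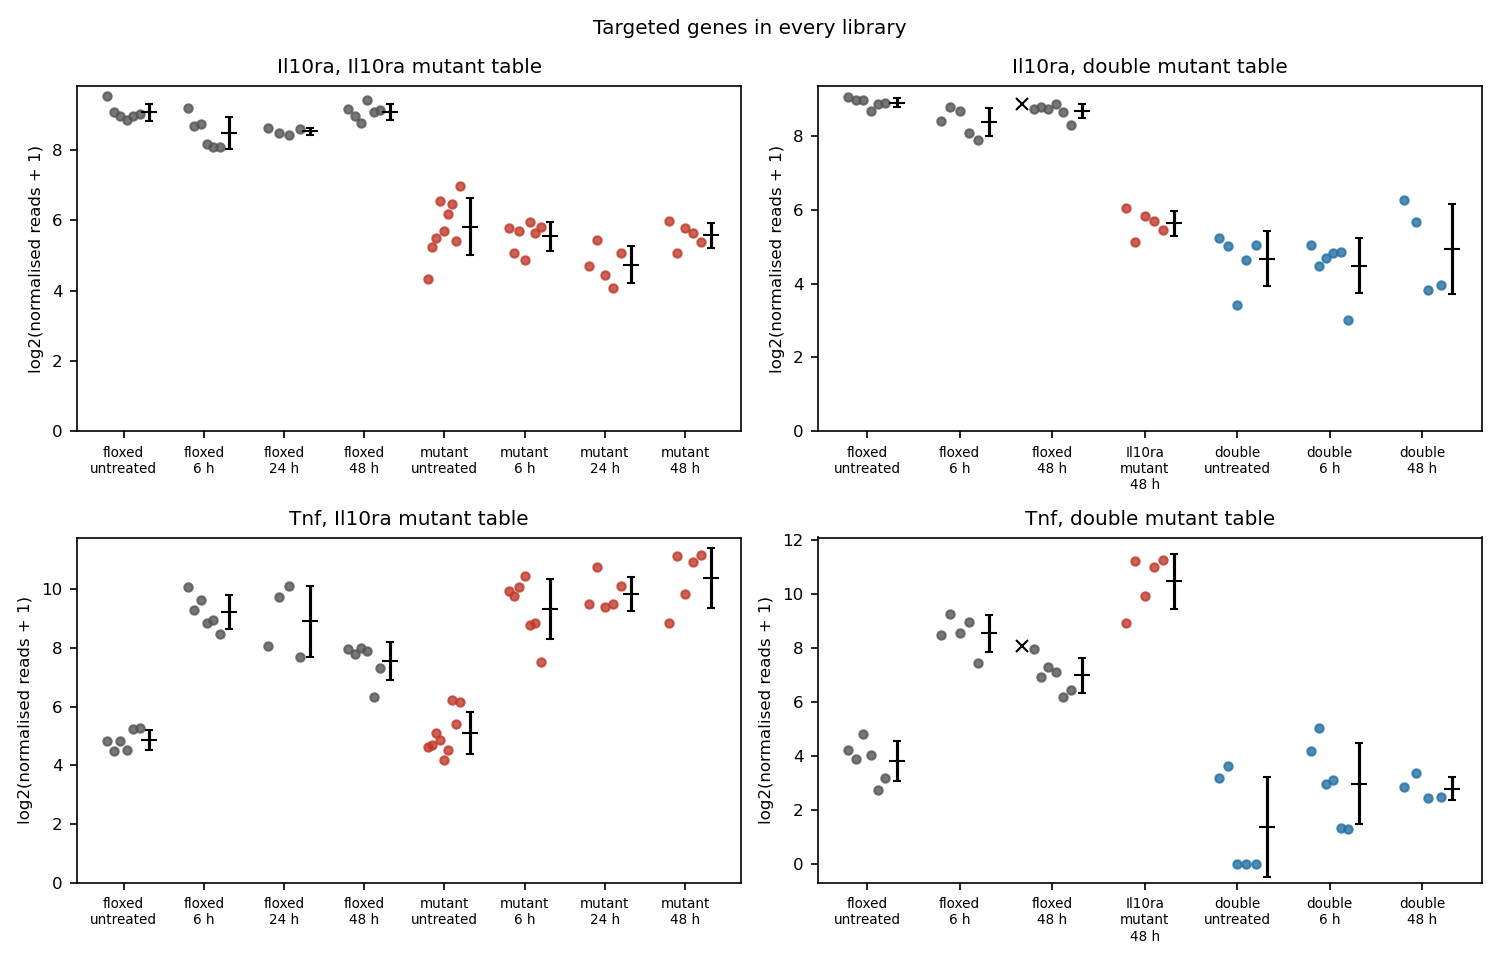
Il10ra and Tnf in each library of the Il10ra mutant table (left) and the double mutant table (right), vertical axis log2 of normalised reads plus 1, dots for libraries, bars for mean ± SD. The cross is the library with conflicting labels, and Il10ra in untreated mutants averaged 63.1 normalised reads against 542 in controls.

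Without LPS (9 mutant against 6 control libraries), the question was what loss of the IL-10 receptor does at rest. Il10ra was the only gene called by limma, with 0 genes higher and 1 lower. Genes at unadjusted p under 0.05 numbered 249, and edgeR and DESeq2 each called 2. The inflammatory gene Tnf did not differ (37.4 ± 21.3 against 28.7 ± 6.86, log2 0.33, adjusted p = 1). Of 6 MHC class II genes 0 passed over all genes and 4 were higher over the list alone (median log2 0.73, camera adjusted p = 3.21e-07, adjusted p = 0.046 with an estimated correlation). Of 24 interferon response genes 0 passed over all genes (0 over the list alone), with a median of log2 0.30 (camera adjusted p = 8.32e-09, adjusted p = 0.313 with an estimated correlation). Cx3cr1, the gene that holds the CreER insertion, had log2 -1.05 and did not pass (adjusted p = 0.0786).

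At 6 h (7 mutant against 6 control libraries) 218 genes were higher and 164 lower in Il10ra mutants. The chemokine Cxcl11 rose from 6.19 ± 5.15 to 40.6 ± 33.1 (log2 2.50 ± 0.51, adjusted p = 0.00588), Il12b by log2 1.64 ± 0.49 (adjusted p = 0.0471) and Il6 from 19.0 ± 12.2 to 53.98 ± 20.2 (log2 1.56 ± 0.40, adjusted p = 0.0208). Stat3, which carries the IL-10 signal, was higher (log2 0.84 ± 0.17, adjusted p = 0.00561). Tnf did not differ (778 ± 434 against 638 ± 267, log2 0.09, adjusted p = 0.928). The mitochondrial transcript mt-Nd1 was called (log2 1.58 ± 0.42, adjusted p = 0.0307), but mitochondrial reads were 0.0512 and 0.2472 percent in controls 1 and 3 against 0.7636 to 1.0363 in the other controls. Without the libraries of low mitochondrial share mt-Nd1 had log2 0.35 and did not pass (adjusted p = 0.425). Of 22 NF-kB target genes 2 rose (3 over the list alone, camera adjusted p = 0.000765, adjusted p = 0.49 with an estimated correlation), and of 19 cytokine genes 2 rose (5 over the list alone, camera adjusted p = 0.00731, adjusted p = 0.605 with an estimated correlation). The count was 1 within the shared experiment with most libraries and 186 without the experiment term, and it ran from 66 without mutant library 5 to 609 without mutant library 7. Higher genes made up 57.1 percent of the calls, and 44.8 percent after quantile normalization.

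At 24 h (5 mutant against 4 control libraries) 405 genes differed in Il10ra mutants, 277 of them lower. The chemokine Ccl22 rose from 15.01 ± 12.5 to 68.4 ± 44.1 (log2 2.53 ± 0.55, adjusted p = 0.0102), Cxcl2 from 57.7 ± 44.2 to 209.5 ± 120 (log2 2.19 ± 0.63, adjusted p = 0.0397) and Cd40 by log2 2.06 ± 0.55 (adjusted p = 0.0279). Cx3cr1 was 697 ± 310 against 2358 ± 1308 in controls (log2 -1.70 ± 0.27, adjusted p = 0.000557). This gene holds the CreER insertion and had log2 -1.05 in mutants without LPS, so its fall is not a response to LPS alone. It is among the 20 homeostatic genes, here and in the other mutant comparisons. The microglial gene Tmem119 was lower by log2 1.03 ± 0.24 (adjusted p = 0.0151). Of 20 homeostatic genes 4 fell (7 over the list alone, median log2 -0.43, camera adjusted p = 5.86e-05, adjusted p = 0.31 with an estimated correlation). Of 19 cytokine genes 1 rose (10 over the list alone, median log2 1.10, camera adjusted p = 8.52e-07, adjusted p = 0.304 with an estimated correlation). The count was 1 within the experiment with most libraries, 681 by DESeq2, 2 without control library 4, 8 without control library 3 and 1541 without mutant library 1. Of 100 splits of the same libraries, the real one included, 10 called as many genes as the genotypes did, so the splits alone did not exclude chance for this count. Of the 277 lower genes 210 were lower again at 48 h in other libraries (42.2 expected for independent genes), and 81 of the higher genes were higher again (16.2 expected). Genes that move together can overlap more than this, so the overlap did not exclude chance either.

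At 48 h the contrast was widest, with 1465 genes higher and 1762 lower in Il10ra mutants. The fold changes rested on 3 mutant and 6 control libraries of the same experiment, and 2 mutant libraries of another experiment are given beside them. Tnf averaged 201 ± 69.0 in controls, 1214 ± 930 in the 3 mutants and 2141 ± 272 in the other two (log2 2.39 ± 0.47, adjusted p = 0.000112). Acod1, which makes itaconate, averaged 13.7 ± 8.24, 490 ± 479 and 919 ± 56.8 (log2 4.50 ± 0.82, adjusted p = 3.71e-05). The neutrophil chemokine Cxcl2 averaged 7.63 ± 4.68, 182 ± 147 and 682 ± 65.2 (log2 4.18 ± 0.65, adjusted p = 2.57e-06), and the BMP antagonist Nbl1 rose from 1.29 ± 2.02 to 145.7 ± 46.7 over all 5 mutants (log2 6.05 ± 0.73, adjusted p = 1.76e-08). The adhesion receptor Adgrg1 fell from 764 ± 95.9 to 105.7 ± 23.9 over all 5 mutants (log2 -2.86 ± 0.27, adjusted p = 5.23e-11). Olfml3 fell to 8.36 ± 2.16 and 12.0 ± 1.91 (log2 -3.82 ± 0.39, adjusted p = 3.03e-10), and Tk1 from 28.6 ± 13.7 to 0.891 ± 0.817 and 3.16 ± 1.96 (log2 -3.89 ± 0.50, adjusted p = 6.4e-08). P2ry12 averaged 1181 ± 366 in controls, 449 ± 173 in the 3 mutants and 342 ± 69.2 in the other two.

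In the same comparison 17 of 20 homeostatic genes fell (17 over the list alone, median log2 -1.38, camera adjusted p = 1.4e-13, adjusted p = 0.0382 with an estimated correlation). Of 15 proliferation genes 13 fell (14 fell and 1 rose over the list alone, median log2 -1.68, camera adjusted p = 2.13e-06, adjusted p = 0.0649 with an estimated correlation). Of 19 cytokine genes 11 rose (11 rose and 1 fell over the list alone, median log2 1.82, camera adjusted p = 1.58e-06, adjusted p = 0.31 with an estimated correlation), and of 22 NF-kB target genes 11 rose (12 over the list alone, camera adjusted p = 7.1e-06, adjusted p = 0.335 with an estimated correlation). Of 18 neurodegeneration-associated genes 9 fell and 3 rose (9 and 3 over the list alone, camera adjusted p = 0.0355, adjusted p = 0.435 with an estimated correlation). Of 10 neutrophil markers 3 rose and 1 fell (5 and 1 over the list alone, median log2 1.63), and the list did not pass (camera adjusted p = 0.361). Mitochondrial reads made up 1.46 ± 0.239 percent of mutant and 0.959 ± 0.347 percent of control libraries. The count of genes was 1987 without mutant library 2, the lowest of all counts with 1 library left out. Of 100 splits of the libraries, the real one included, only the real one called as many genes, and the highest other called 2072. That split exchanged nearly all controls with all mutants. It was close to the real split with its sides reversed, so 2072 does not measure chance.

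The test of whether LPS itself acted differently by genotype was made at 48 h only. The interaction was called for 1893 genes, 779 above and 1114 below 0. Nbl1 (log2 6.95 ± 0.92, adjusted p = 7.72e-07), Acod1 (log2 5.33 ± 1.04, adjusted p = 0.000256) and Tnf (log2 2.06 ± 0.60, adjusted p = 0.0119) responded more in mutants. Tk1 (log2 -4.39 ± 0.63, adjusted p = 2.81e-06), Olfml3 (log2 -3.80 ± 0.49, adjusted p = 4.2e-07) and P2ry12 (log2 -1.31) were below 0, and Il10ra did not differ (log2 -0.23, adjusted p = 0.757). Of 20 homeostatic genes 14 were below 0 (15 over the list alone, camera adjusted p = 2.67e-12, adjusted p = 0.0496 with an estimated correlation). Of 15 proliferation genes 11 were below 0 (13 over the list alone, camera adjusted p = 1.12e-07, adjusted p = 0.046 with an estimated correlation). The count was 1134 without mutant library 2 at 48 h.

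**Figure D3:**
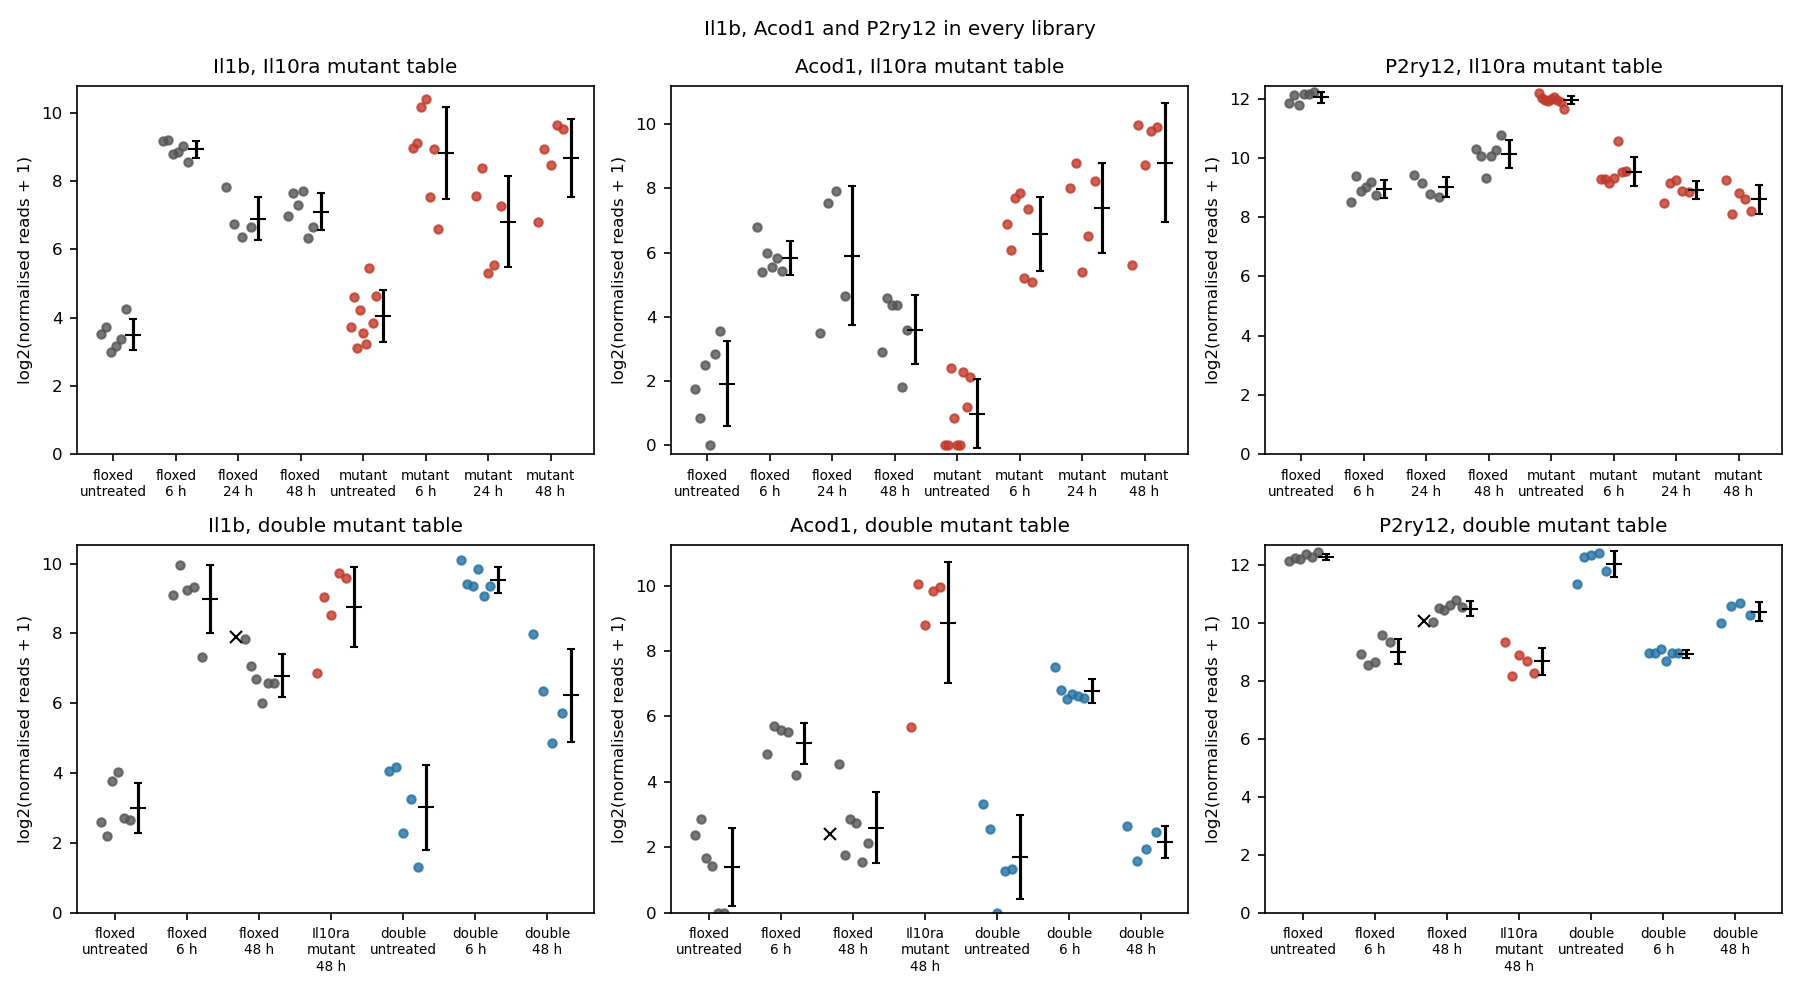
Il1b, Acod1 and P2ry12 in each library of the Il10ra mutant table (top) and the double mutant table (bottom), vertical axis log2 of normalised reads plus 1, dots for libraries, bars for mean ± SD. In the double mutant table Acod1 averaged 692 normalised reads in Il10ra mutants and 3.68 in double mutants at 48 h.

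The double mutants asked whether the Il10ra phenotype persists without Tnf. Without LPS (5 against 6 libraries) limma called 0 genes higher and 3 lower, namely Il10ra, Tnf and Cx3cr1, with 1077 genes at unadjusted p under 0.05. Cx3cr1, in which CreER is inserted, fell from 5260 ± 377 to 2286 ± 1031 (log2 -1.34 ± 0.20, adjusted p = 0.000363). Without double mutant library 2 the untreated count was 7. At 6 h (6 against 5 libraries) 3 genes were higher and 5 lower, with 1374 at unadjusted p under 0.05, 17 by edgeR and 1.1e+02 by DESeq2. Socs1, which restrains cytokine signalling, rose from 34.4 ± 9.48 to 93.7 ± 39.7 (log2 1.41 ± 0.28, adjusted p = 0.027), and Cx3cr1 fell by log2 1.49 ± 0.20 (adjusted p = 2.05e-05). Of 24 interferon response genes 0 passed over all genes and 12 were higher over the list alone (median log2 0.70, camera adjusted p = 3.14e-14, adjusted p = 0.0606 with an estimated correlation). At 6 h the count was 14 within the experiment with most libraries, 4 without the experiment term and 1.1e+02 without double mutant library 3.

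At 48 h (4 double mutant against 6 control libraries) limma called 0 genes higher and 2 lower, and these were Tnf and Il10ra. Genes at unadjusted p under 0.05 numbered 393, and edgeR called 2 and DESeq2 3. Acod1 averaged 3.68 ± 1.501 in double mutants and 6.98 ± 7.72 in controls, P2ry12 1366 ± 292 and 1456 ± 233, and Adgrg1 634 ± 41.6 and a mean of 652. Of 20 homeostatic genes 0 passed (1 lower over the list alone, median log2 -0.03, camera adjusted p = 0.339). Of 19 cytokine genes 1 was lower, Tnf itself (median log2 -0.11, camera adjusted p = 0.03, adjusted p = 0.632 with an estimated correlation), and of the proliferation genes 0 passed (median log2 -0.43, camera adjusted p = 0.00122, adjusted p = 0.378 with an estimated correlation). Changes given to simulated reads were found for 42.6 percent of genes at log2 1 and 91.8 percent at log2 2, so smaller differences may have gone unseen. The simulated reads lacked the structure that real libraries share, so these percentages may be too high.

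In the same table Il10ra mutants at 48 h were set against the doubly floxed controls. On the mutant side the fold changes rested on 2 libraries of one experiment. All 6 control libraries, 4 of them of that experiment, entered with the additive experiment term. The fold changes therefore need not match the averages within that experiment. There were 1954 genes higher and 2045 lower in the mutants. Mitochondrial reads made up 1.1522 and 1.2872 percent of the 2 mutants and 1.8458 to 2.6116 percent of the 4 controls of that experiment, the reverse of the first table. Within that experiment Acod1 averaged 9.16 ± 8.95 in controls and 959 ± 61.0 in mutants (log2 6.98 ± 0.70, adjusted p = 5.23e-10), Tnf 163.5 (lowest 119.2, highest 246.1) and 2235 ± 288 (log2 3.65 ± 0.57, adjusted p = 3.91e-06) and Cxcl2 15.7 ± 16.2 and 713 ± 69.3 (log2 5.56 ± 0.73, adjusted p = 1.62e-07). The topoisomerase Top2a fell from 114.4 ± 32.1 to 4.82 ± 2.34 (log2 -4.45 ± 0.64, adjusted p = 9.27e-07) and Adgrg1 from 604 ± 47.4 to 108.2 ± 11.8 (log2 -2.53 ± 0.18, adjusted p = 1.72e-13). Of 20 homeostatic genes 15 fell (16 over the list alone, median log2 -1.63, camera adjusted p = 1.2e-13, adjusted p = 0.031 with an estimated correlation). Of 22 NF-kB target genes 20 rose (20 over the list alone, camera adjusted p = 1.23e-13, adjusted p = 0.0788 with an estimated correlation). Of 18 proliferation genes 14 fell (15 over the list alone, median log2 -3.71, camera adjusted p = 4.71e-09, adjusted p = 0.0788 with an estimated correlation). The count was 2203 without mutant library 5.

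Double mutants were compared with Il10ra mutants directly at 48 h, 4 against 5 libraries, of which 2 and 2 shared an experiment. On the Il10ra mutant side the fold changes rested on the 2 libraries of the shared experiment, because the other 3 stood alone in theirs. The other 2 double mutants entered the fold changes through the additive experiment term, so these need not match averages of the shared experiment. There were 1757 genes higher and 1613 lower in double mutants. Within the shared experiment Tnf averaged 2235 ± 288 in Il10ra mutants and 7.73 ± 2.18 in double mutants (log2 -7.59 ± 0.62, adjusted p = 4.33e-12), and Acod1 959 ± 61.0 and 3.64 ± 2.34 (log2 -7.23 ± 0.75, adjusted p = 1.47e-09). Cxcl2 averaged 713 ± 69.3 and 18.8 ± 20.9 (log2 -5.70 ± 0.79, adjusted p = 5.3e-07), Adgrg1 108.2 ± 11.8 and 634 ± 32.6 (log2 2.48 ± 0.20, adjusted p = 2.4e-12). Il10ra did not differ (log2 -0.28, adjusted p = 0.642). Of 20 homeostatic genes 15 were higher in double mutants (15 over the list alone, median log2 1.52, camera adjusted p = 1.23e-13, adjusted p = 0.031 with an estimated correlation). Of 19 cytokine genes 14 were lower (14 over the list alone, median log2 -3.08, camera adjusted p = 1.1e-10, adjusted p = 0.0739 with an estimated correlation), and 14 of 18 proliferation genes were higher (14 over the list alone, median log2 3.27, camera adjusted p = 1.66e-07, adjusted p = 0.135 with an estimated correlation). The count was 1791 without mutant library 5.

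**Figure D4:**
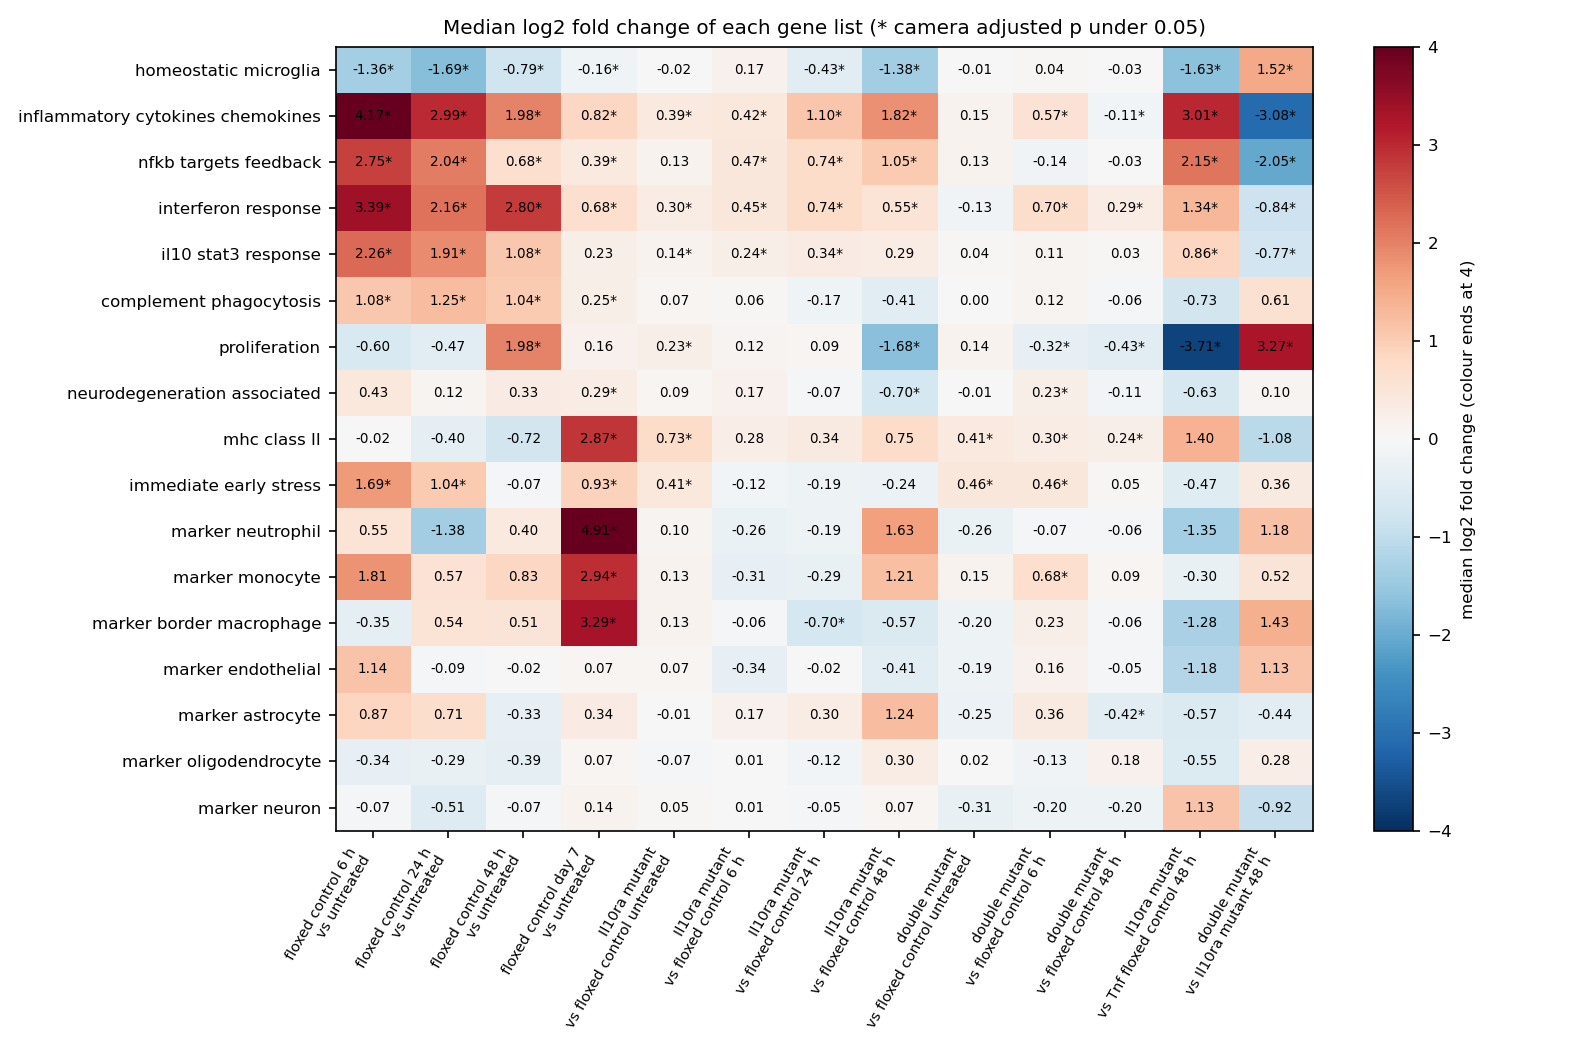
Median log2 fold change of 17 gene lists in 13 comparisons, asterisk for camera adjusted p under 0.05 with the preset correlation, colour scale in log2 ending at 4. Homeostatic microglia genes stood at -1.38 in Il10ra mutants and -0.03 in double mutants at 48 h.

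The ATAC libraries of C57BL/6 microglia asked where chromatin was open without LPS and 12 h, 24 h and 2 weeks after it. The untreated libraries were 4 samples with 2 sequencing runs each, averaged here, and each later time had 4 samples. Peaks per sample averaged 1981 ± 2970 without LPS, 17382 ± 14749 at 12 h, 25717 ± 4576 at 24 h and 19162 ± 14318 at 2 weeks. The 24 h and 2 week groups differed from untreated (exact permutation p = 0.0286 and 0.0286, adjusted 0.0429 for each), and 12 h did not (exact permutation p = 0.0857). These peaks were left after filtering against the library's own tags, which removed 67.2 to 100 percent of the putative peaks. Putative peaks averaged 27616 ± 13095 without LPS and 105587 ± 15964 at 24 h. The mean at 24 h was 3.82 times that without LPS in putative peaks, against 12.98 times in the peaks kept. Untreated samples also had fewer tags, 0.485 of the mean of the later libraries, but peaks did not follow tags in each library. With 7629951.5 tags 24 h sample 1 had 24491 peaks, against 7654 with 8598043.5 tags in the first run of untreated sample 1. The 2 week difference did not pass with the first untreated runs only (exact permutation p = 0.0857). Nor did it pass with any single untreated sample left out (exact permutation p = 0.0857 to 0.1143). The lowest 2 week sample had 6342 peaks, and the highest untreated sample averaged 6319. Over all pairs, peak positions overlapped more within a group than between groups, 43.9 against 38.6 percent (difference 5.34, exact permutation p = 7.04e-05, 14 samples with enough peaks). These shares depend on the lengths of the lists. With 1185 peaks from each library they were 24.0 and 18.3 percent (exact permutation p = 0.0145), and the 24 h samples shared 35.1 ± 3.70 percent, above their overlap with any other group. The other groups did not stand apart, with 20.5 percent within 12 h against 23.6 with 24 h, 17.8 within 2 weeks against 19.2 with 12 h and 15.5 in the single untreated pair against 14.9 with 2 weeks. Repeat runs of one sample also overlapped only in part. In full lists of untreated sample 1, 41.2 percent of second-run peaks lay in the first run and 27.8 percent the reverse. For untreated sample 2 these were 26.4 and 19.6 percent. Of 18570 regions seen in at least 2 samples at 2 weeks, 12664 (68.2 percent) were also seen at 24 h, 50.8 percent at 12 h and 6.3 percent without LPS. Conversely, 79.8 percent of the 1463 untreated regions were seen at 2 weeks, so these shares too depend on list length. A region on chromosome 13 from 9010959 to 9011125 (mm9) was among 76 found in all 14 samples.

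**Figure D5:**
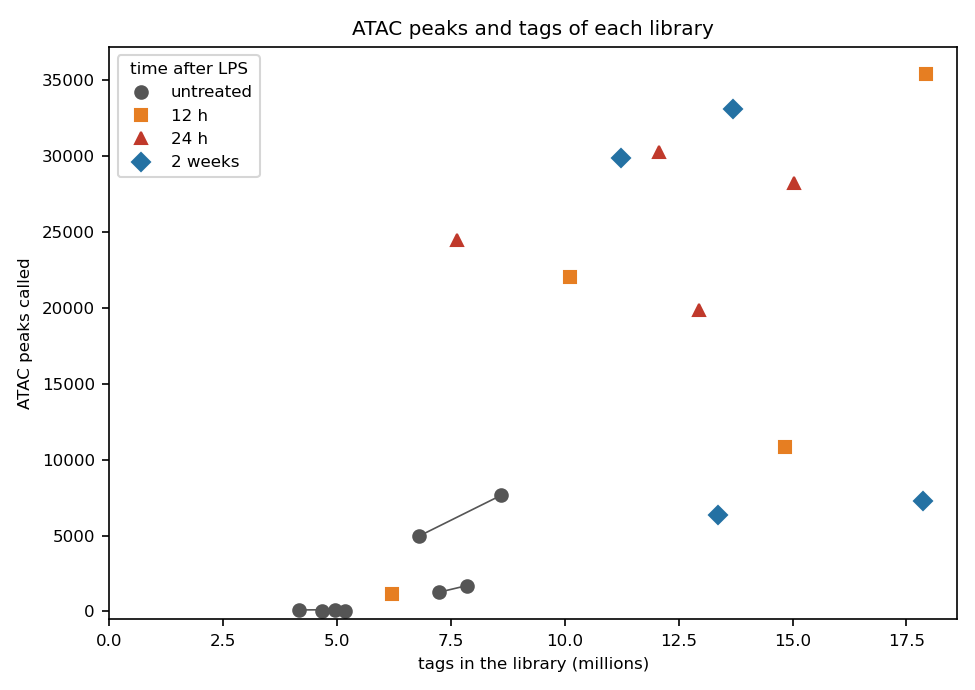
Peaks called against tags for each of the 20 ATAC libraries, with lines joining the 2 runs of one untreated sample. Mean peaks were 1981 without LPS and 25717 at 24 h.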

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

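The tests of the 3 patterns below were chosen after the results were seen, and the splits of libraries were planned before. An outlier test on each set of libraries marked 12 single values, where chance alone marks about 1 in 20. Cx3cr1 was 4790.1 in day 7 library 1 (others 6012.0 to 6258.4). Il10ra was 744.6 in untreated control 1 (others 457.2 to 541.1), and the mitochondrial share of the same library was 0.195 percent (others 0.924 to 1.103). P2ry12 was 1544.2 in Il10ra mutant 5 at 6 h (others 565.5 to 764.3) and 407.7 in double mutant 4 at 6 h (others 493.9 to 541.0). S100a8, a neutrophil gene, was 661.1 in Il10ra mutant 1 at 6 h, 2030.0 and 449.1 in doubly floxed controls 3 at 6 h and 2 at 48 h, 232.0 in untreated double mutant 3 and 2.4 in C57BL/6 library 1. Nearest other S100a8 values were 254.1, 79.2, 160.7, 11.3 and 0. The mitochondrial share was 0.095 percent in untreated double mutant 1 (others 0.959 to 1.273) and 2.382 percent in double mutant 2 at 48 h (others 1.353 to 1.503).

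The LPS response at 48 h differed between Il10ra mutants and controls for 1893 genes, with Tnf at log2 2.06 and P2ry12 at log2 -1.31. In the library with conflicting labels, which was left out, Il10ra was 466.6, Tnf 266 and Cx3cr1 4049 normalised reads.

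The difference of Il10ra mutants from controls at 48 h could come from the CreER allele or from neutrophils in the sort. Its fold changes rested by design on libraries of the same experiment. Genes called in the mutants had a median signed change of log2 0.01 in double mutants, which carry the same allele. In the mutants, where these genes were selected, it was log2 1.03. This argued against an allele effect that does not depend on Tnf. The double mutants also lack Tnf, and no group carried the allele without the Il10ra deletion. An allele effect that acts through Tnf could therefore not be told from loss of Il10ra. The neutrophil markers had a median of log2 1.63 in the first table and log2 -1.35 against the doubly floxed controls. These comparisons used different mutant and control libraries, and S100a8 was an outlier at 449.1 in doubly floxed control 2. These medians therefore could not tell whether neutrophils contributed in the first table. With the neutrophil marker mean as a covariate, 3010 of the 3227 reported genes were called again. This argued against neutrophils as the source of most of these genes, as far as that mean tracks them. A part in the remaining genes was left open.

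The rise of blood and border cell genes at day 7 could reflect a lower share of microglia, blood cells carried along in the sort, or the separate experiment. The highest median among astrocyte, oligodendrocyte, neuron and endothelial markers was log2 0.34, against log2 2.94 for the lowest of the blood and border lists. This argued against a like rise of those other cell types. The sort on CD45 and CD11b selects against them, so a lower share of microglia through blood and border cells was left open. With the neutrophil marker mean as a covariate 7 genes were left, but 77 percent of the variance of that covariate lay between the groups, so the test could not tell. The day 7 experiment held 0 untreated libraries, so its effect could not be told from that of time. Hbb-bs and Fosb were also higher in untreated C57BL/6 libraries of another separate experiment (log2 5.95 and 4.23), while 3 of 6 neutrophil markers were lower there.

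The smaller number of ATAC peaks without LPS could follow from sequencing depth. Untreated samples had 0.485 of the mean tags of the LPS libraries, so lower depth remains a possible cause, and 12 h sample 2 with 6208254 tags had 1185 peaks. Other libraries went against it. With 7629951.5 tags 24 h sample 1 had 24491 peaks, while the first runs of untreated samples 1 and 2 had 7654 and 1710 with 8598043.5 and 7855249 tags, and 2 week sample 1 had 7295 with 17871104. With so few samples of like depth in both groups the question stayed open. Tags in peaks were also few in untreated samples, 0.402 percent on average against 4.86 percent at 24 h. Whether the quality of the untreated libraries lowered their peaks was not tested. The run of the LPS libraries is not given in the labels, and no effect of the run was tested.

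Each set of called genes was compared with 100 splits of the same libraries, the real one included. Only the real split (1 of 100) called as many genes in the controls at 6 h (highest other split 1950), 24 h (1773), 48 h (772) and day 7 (334). The same held for Il10ra mutants at 6 h (195) and 48 h (2072), Il10ra mutants against doubly floxed controls (2375), double against Il10ra mutants (2895) and C57BL/6 against floxed controls (92). In controls at 24 h and against doubly floxed controls, the highest other split exchanged a single library of each group. In the rest of these comparisons it nearly exchanged the whole groups. These highest values therefore kept much of the real difference and do not measure chance. The median other split called 0 genes. Splits as large numbered 3 for the interaction (highest other 2350) and 3 for untreated double mutants (highest other 7). The split of the interaction that called 2350 moved untreated libraries only and kept the real groups at 48 h. It therefore kept the genotype difference at 48 h and does not measure chance. For the number of called genes alone, the splits did not exclude chance in untreated Il10ra mutants (9 splits as large, highest other 2), Il10ra mutants at 24 h (10, highest other 2513), double mutants at 6 h (6, highest other 209) and double mutants at 48 h (6, highest other 10). This did not extend to the targeted genes. Il10ra had limma adjusted p = 3.69e-13 in untreated mutants, where no mutant library exceeded 123.6 and no control lay under 268.5. In double mutants Tnf and Il10ra had limma adjusted p = 2.85e-12 and 2.53e-13 at 6 h and 7.13e-07 and 2.9e-11 at 48 h. Of the 277 genes lower in mutants at 24 h, 210 were lower again at 48 h in other libraries (42.2 expected for independent genes). Genes moved together in the splits, so this overlap did not exclude chance at 24 h either. At 24 h the split that exchanged control 2 and mutant 1 called 2513 genes where the genotypes called 405, and the counts without these libraries were 1385 and 1541. In double mutants at 6 h the split that exchanged control 5 and double mutant 4 called 209 where the genotypes called 8. Such counts point to a structure of the samples, but what set these libraries apart was not tested.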

How the results depend on the processing

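Of 18455 values of named genes under other settings 17261 stayed the same, 1180 were weaker, 10 stronger and 4 reversed. Reversed were S100a8 (log2 -0.96), S100a9 (log2 -0.86) and Saa3 (log2 -0.35) at day 7 with the neutrophil covariate, and Stab1 (log2 0.01) in Il10ra mutants against doubly floxed controls without the experiment term. S100a8 and S100a9 are part of that covariate, and neither they (adjusted p = 0.947 for each) nor Saa3 (adjusted p = 0.989) passed with it. Causes were not tested. The covariate, the other shared experiment and the omission of libraries of low mitochondrial share were chosen after the data were seen. Within the shared experiment with most libraries controls gave 3048 genes at 6 h and 1793 at 24 h, and the covariate left 7 at day 7. After rescaling to the upper quartile the median of all genes at 6 h shifted to log2 -0.137.

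Untreated Il10ra mutants gave 2 genes without the experiment term, 2 by edgeR, 2 by DESeq2, 2 without libraries of low mitochondrial share and 3 in the other shared experiment. At 6 h they gave 186 without the experiment term, 253 by edgeR, 1 in the shared experiment with most libraries and 220 in the other, and at 24 h 681 by DESeq2, 1 and 995, the last with a single control library. Double mutants at 6 h gave 13 with a pseudocount of 5, 4 without the experiment term, 14 and 3 in the shared experiments, 17 by edgeR and 1.1e+02 by DESeq2. At 48 h Il10ra mutants gave 4285 genes within the shared experiment, 4015 without its term, 3895 by edgeR and 3240 with the covariate, and 3118, 2907, 3203 and 3010 of the 3227 reported genes were called again. Of the gene list calls 16 were left with an estimated correlation.

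With each library left out in turn controls gave 3856 to 4614 genes at 6 h, 2413 to 3721 at 24 h, 1390 (untreated 4) to 2215 at 48 h and 231 (day 7 library 1; 302 without library 2) to 465 at day 7. Il10ra mutants gave 1 to 3 untreated (3 without mutant 1), 66 to 609 at 6 h, 2 to 1541 at 24 h and 1987 (mutant 2) to 3196 at 48 h. At 6 h controls 2, 4, 5 and 6 gave 600, 1.5e+02, 212 and 228, and mutants 1, 5, 6 and 7 gave 210, 66, 254 and 609. At 24 h controls 1 to 4 gave 748, 1385, 8 and 2, and mutants 1 to 5 gave 1541, 141, 171, 96 and 1.3e+02. The interaction gave 1134 (mutant 2) to 2012. Double mutants gave 2 to 7 untreated (7 without mutant 2), 5 to 1.1e+02 at 6 h and 2 to 3 at 48 h. At 6 h doubly floxed controls 3 and 5 gave 17 and 14, and double mutants 1 to 5 gave 5, 5, 1.1e+02, 30 and 5. Il10ra mutants against doubly floxed controls gave 2203 (mutant 5) to 4025, double against Il10ra mutants 1791 (mutant 5) to 3400, and C57BL/6 against floxed controls 727 to 1188.

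The ATAC peak difference at 12 h was 15400.4, and 9382.6 to 20799.3 with a library left out (exact p = 0.0286 at 20799.3, without 12 h sample 2). At 24 h it was 23735.1, and 22219.6 to 25685.6. At 2 weeks it was 17180.4, and 12529.6 to 21453.6. It was 16789.0 with the first run only (exact p = 0.0857), 18626.2 without untreated sample 1 (exact p = 0.0857) and 17016.6, 16521.9 and 16556.8 without samples 2, 3 and 4 (exact p = 0.1143 each). The overlap difference of 5.34 was 3.96 to 6.9 with a sample left out, 4.68 with 0.5 of the shorter peak, 5.72 with equal numbers of peaks and 4.46 with at least 5000 peaks.

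The shared replicate numbers do not pair the samples. With the number as a replicate block the count was 177 for Il10ra mutants at 24 h and 2181 for double against Il10ra mutants, and it moved no other count by more than 1.5 times. In no comparison did every pair of a number correlate over 0.1 or every sample correlate best with its own number.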

Other observations

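Untreated C57BL/6 microglia (4 libraries) differed from untreated floxed controls (6 libraries) by 601 genes higher and 409 lower, across experiments that shared no group. The scaffold gene Lrba was 325.5 ± 20.1 against 16.9 ± 5.27 normalised reads (log2 4.24 ± 0.22, limma adjusted p = 4.62e-13), and Mlph was lower (log2 -1.99 ± 0.11, adjusted p = 7.07e-13). Tnf was 74.0 ± 17.1 against 26.8 ± 6.399 (log2 1.44 ± 0.31, adjusted p = 0.00252). The haemoglobin genes Hbb-bs (log2 5.95, adjusted p = 0.000841), Hba-a1 (log2 5.60, adjusted p = 0.000101) and Hba-a2 (log2 4.99, adjusted p = 0.000383) were among the largest rises. All 15 immediate early genes were higher (15 over the list alone, median log2 2.25, camera adjusted p = 1e-24, adjusted p = 0.0416 with an estimated correlation), and 13 of 22 interferon response genes were higher (13 over the list alone, camera adjusted p = 6.59e-13, adjusted p = 0.0416 with an estimated correlation). Of 6 neutrophil markers 3 were lower (5 over the list alone, camera adjusted p = 0.000438, adjusted p = 0.147 with an estimated correlation).

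The 48 h comparisons of Il10ra mutants in the first and second tables rested on different mutant and control libraries. Of 11189 genes tested in both, 899 were higher in both (248.7 by chance) and 1136 lower in both (307.1 by chance), and log2 fold changes correlated with r = 0.753. Of 277 genes lower in mutants at 24 h, 210 were lower at 48 h (42.2 by chance), and 81 genes were higher at both times (16.2 by chance). Of 218 genes higher at 6 h, 53 were higher at 48 h (27.6 by chance) and 23 lower, and of 164 lower genes 68 were lower (25 by chance). All these numbers by chance take genes as independent, and genes that move together can overlap more. Log2 fold changes at 48 h correlated with r = 0.229 at 6 h and 0.557 at 24 h. In untreated double mutants Cx3cr1 was 1162 and 1155 in libraries 1 and 5 and 2929 to 3102 in the other 3. ATAC regions seen in at least 2 samples numbered 1463 without LPS, 15425 at 12 h, 22673 at 24 h and 18570 at 2 weeks, and 8075 were seen in at least 2 samples of each LPS group.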
